A study of Streptomyces coelicolor with 4 samples.

How the data were processed

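Chromatin immunoprecipitation on DNA arrays (ChIP-chip) was used to look for places on the chromosome of Streptomyces coelicolor that were recovered with an antibody against BldD. Streptomyces coelicolor is a filamentous soil bacterium, and BldD is a DNA-binding regulator of its development. Per the labels, 3 arrays came from the wild-type strain M600, grown in triplicate, and 1 array from a bldD null mutant. All cultures were in log phase in YEME/TSB liquid medium. Per the labels' protocols, cultures were fixed with 1% formaldehyde for 30 min and 800 ng of DNA was labelled. On every array the immunoprecipitated DNA carried Cy3 and the total DNA of the same strain carried Cy5, per the labels, so no dye swap was made. The mutant lacks the antibody's target and is the control for DNA recovered for other reasons.

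The deposited table analysed here gives, for each probe, a p-value and an adjusted p-value, per the file headers. It gives no intensity, ratio or fold change and no value for a single array. The authors' test, whether it was one-sided or two-sided, the groups it set against each other, the array normalization and the genome build are not given in the sources used here. The probe names hold the position on a single sequence and the probe's orientation, since the larger coordinate comes first for some probes, called reverse here. The deposited adjusted p-value differed by at most 8.4e-06 from a Benjamini-Hochberg adjustment recomputed over all 36043 deposited p-values. No column of per-sample values was left out (0 columns).

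Before the data were examined, a limma model of log2 ratios per probe and per promoter had been planned, with camera tests of 15 gene lists, correlations between arrays and the position of summits relative to genes. None of these was run, because they need a value for each array or gene positions on the same build. The reference table at hand describes the assembly ASM4782426v1 of strain M1152, another build, so its coordinates were not used and no gene was assigned to a position. The deposited adjusted p-value took the place of the planned test, with the planned threshold of 0.05. No minimum fold change could be applied. The rule for what the text names was the 25 regions with the largest difference at the summit. It became the 25 regions with the lowest summit p-value. The probes at the opposite end of the p-value scale took the place of the strongest negative differences. They can stand for such differences only if the authors' test was one-sided, which is not given in the sources used here.

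Probes with an adjusted p under 0.05 were called. Called probes were joined where the midpoints of successive called probes lay at most 1000 bp apart, and a region needed at least 2 called probes. The summit of a region was the probe with its lowest p-value. Positions are 1-based, as the probe names give them. Called probes that stood alone were kept apart as lone probes. Adjacency of called probes was tested against 100000 random placements of the same number of probes. Positions of summits were tested by circular shifts, in which all summits were moved together along the ordered probes by every possible number of steps (36043 shifts, the observed placement included). Such shifts keep the spacing of the summits. The chromosome core was taken as 1.5 to 6.4 Mb, after the published description of the A3(2) chromosome, and the rest as arms. This choice, and every test of position or orientation, was made after the data had been seen. For centring along the chromosome, each p-value was turned into a normal score and the running median of 200 probes on either side was subtracted.

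Some of the steps were tested on simulated data. Of 50 planted regions among 36043 probes, 50 were recovered and 0 false regions were called. The background was drawn from uncalled probes and the planted p-values were very low, so this outcome was largely set in advance. It does not show how well weaker regions are found. The band found by the scan for shifted p-values and the planted band overlapped over 99.1% of the longer of them. That band was planted among p-values in random order, without the drift along the chromosome. Circular shifts gave p under 0.05 in 2% of 200 random placements. This was done only for the one-sided count of summits near reverse-to-forward changes of probe orientation. The core count and the neighbours of lone probes were not tested in this way. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

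The number of arrays limits the precision. An exact permutation of 3 arrays against 1 cannot give a p below 0.25, so the very small deposited p-values rest on the authors' model of the spread, which could not be examined here. No spread between the wild-type arrays could be computed, and leaving out an array was not possible. Alternatives tried were other thresholds, other gaps and minimum probe numbers, a Bonferroni adjustment, centring and rescaling of the p-values along the chromosome, and leaving out a band of lowered p-values.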

Results

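The series compared DNA recovered with a BldD antibody in wild-type Streptomyces coelicolor M600 with DNA recovered in the same way from a bldD null mutant. The question was where on the chromosome BldD is bound in growing hyphae. There were 3 wild-type arrays and 1 mutant array, each with the strain's own total DNA in the other channel. The authors' deposited table covers 36043 probes of 60 bases from position 21651 to position 8666842 of the sequence it calls chr1. The median distance between successive probe starts was 220 bp, with a 5th percentile of 60 bp and a 95th percentile of 466 bp. The largest distance between successive probes was 6423 bp. The table holds a p-value and an adjusted p-value for each probe, and no fold change or value per array. Sizes of enrichment, their errors and a check of the bldD locus in each array are therefore not given here. Which direction a low p-value stands for is not stated either, so probes with a low adjusted p are described as called, not as enriched. The genome build is not given in the sources used here, and places are named by position only.

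Probes called at the deposited adjusted p were few and concentrated in short stretches of the chromosome. In the authors' deposited table, 273 probes (0.757%) had an adjusted p under 0.05, and 143 of these had an adjusted p under 1e-06. The called probes were neighbours far more often than chance placement gives. There were 168 adjacent pairs of called probes, against a mean of 2.07 and a highest value of 11 in 100000 random placements (permutation test, one-sided p = 1e-05, the smallest these placements can give). Called probes fell into 103 groups, of which 64 were regions with at least 2 called probes and 39 were lone probes. The 64 regions held 234 of the called probes (85.7%). They covered 48.8 kb, or 0.565% of the probed span. The counts depended on the scale of the p-values: centred along the chromosome and rescaled to their own spread, they gave 1547 called probes and 310 regions.

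**Figure D1:**
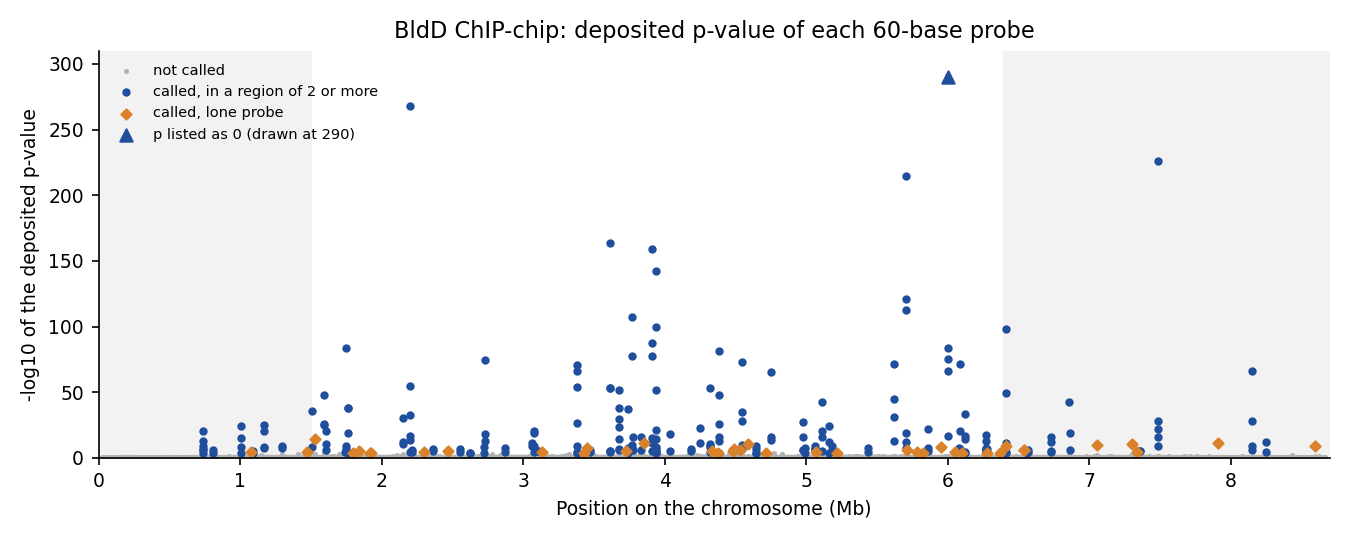
Each point is a probe, with its position on the chromosome in Mb on the horizontal axis and the -log10 of its deposited p-value on the vertical axis. Blue points are called probes in the 64 regions, orange diamonds are the 39 lone probes, grey points were not called, the triangle is the probe listed at a p of 0, and grey shading marks the arms outside 1.5 to 6.4 Mb; the lone probes all lie low on the axis.

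The strongest region lay at positions 5998831 to 5999775, where all 5 probes were called. Its summit probe, at 5999556 to 5999615, is listed at a p of 0 in the authors' deposited table. The region at 2201961 to 2203237 followed, with 6 called probes and, in the authors' deposited table, a p of 1.67e-268 at its summit (2202818 to 2202877). The authors' deposited table gives a summit p of 1.64e-226 for the region at 7487987 to 7488918 (5 called probes) and of 5.38e-215 for that at 5705103 to 5706367 (6 called probes). Then came 4 regions between 3.5 and 4.0 Mb with 6 called probes each. Their summit p-values in the authors' deposited table were 1.22e-164 at 3614784 to 3615915, 1.16e-159 at 3909540 to 3910717, 1.23e-142 at 3935443 to 3936554 and 2.53e-108 at 3771483 to 3772682. The window from 3.5 to 4.0 Mb held 8 regions and 42 called probes, more of each than any other 0.5 Mb window.

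**Figure D2:**
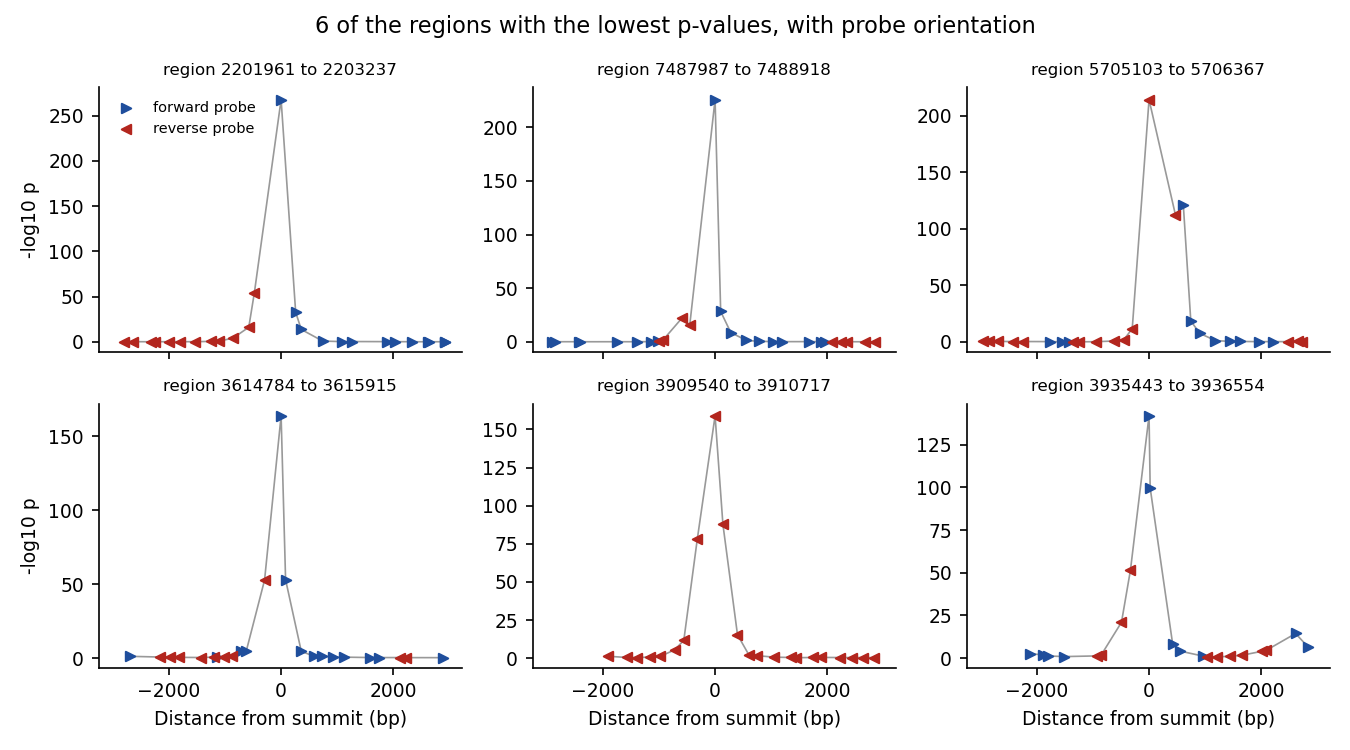
The -log10 of the deposited p-value is plotted against the distance from the summit in bp for the 6 regions ranked after the probe listed at 0. Blue triangles pointing right are forward probes and red triangles pointing left are reverse probes; in 5 of the panels the probe orientation changes from reverse to forward inside the region.

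A second set of regions had summit p-values from 1.61e-98 to 1.03e-37 in the authors' deposited table. In order of rising p, these lay at 6411758 to 6413174, 1744281 to 1745435, 4384032 to 4385013, 2727675 to 2727974, 4545347 to 4546431 and 5620769 to 5621684. They were followed by 6083353 to 6084401, 3380235 to 3381523, 8150439 to 8151399, 4754151 to 4754755, 4318834 to 4319965 and 3674467 to 3676533. The last of these 25 regions lay at 1592024 to 1592664, 6860676 to 6861164, 5108432 to 5109152, 1764058 to 1764762 and 3738777 to 3739819. The 25 regions had a median of 5 called probes and a median width of 1049 bp. The other 39 regions had a median of 2 called probes and a median width of 502 bp. Regions were ranked by summit p and bounded by a fixed threshold, so a stronger summit tends to bring more called probes and a wider region. The difference is therefore in part set by the ranking.

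Most regions were narrow. The median width over all 64 was 706 bp, with quartiles of 428 and 983 bp, and in 62 of the 64 every probe inside the region was called. The number of called probes was 2 in 22 regions, 3 in 12 regions and 4 or more in 30 regions. The widest region, at 6271860 to 6274779 (2920 bp), held 10 called probes among 14. It was not among the strongest, with a summit p of 3.43e-13 in the authors' deposited table. Another region lay just before it, at 6270260 to 6270659, and a lone called probe followed at 6275999. The region at 3674467 to 3676533 was the next widest (2067 bp).

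The p-values rose with distance from the summits. Over the 64 regions, probes within 250 bp of a summit had a median p of 6.43e-08 in the authors' deposited table (55 probes beside 49 summits). The median from the authors' deposited table was 0.00037 at 250 to 500 bp, 0.0407 at 500 to 750 bp and 0.261 at 750 to 1000 bp. At 1750 to 2000 bp it was 0.475, with quartiles of 0.387 and 0.548, against medians of 0.512 over all probes and 0.454 over the core, where most regions lay, in the authors' deposited table. The share of probes with p under 0.05 fell from 98.2% within 250 bp to 5.19% at 1000 to 1250 bp, against 1.49% of all probes. Regions were chosen for at least 2 called probes at most 1000 bp apart, so the low values at the summit and in the nearest bins are in part set by that choice.

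**Figure D3:**
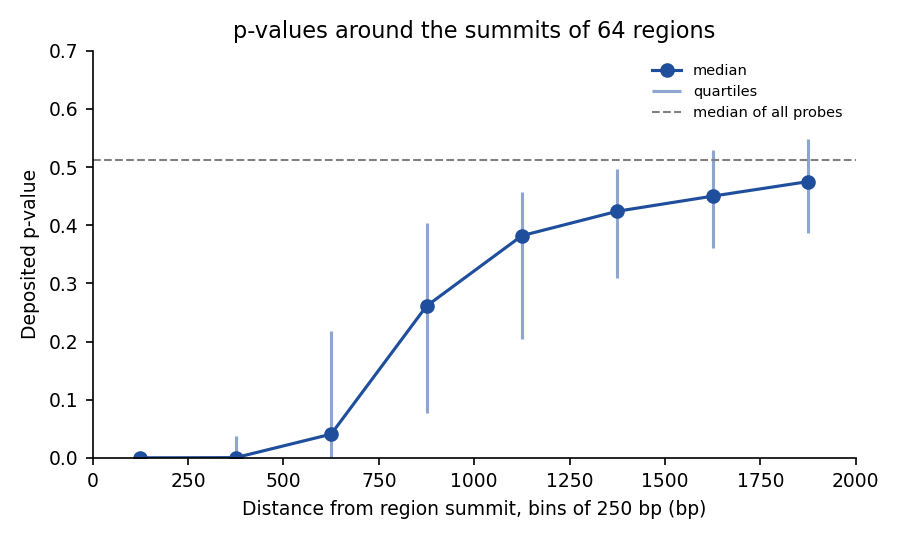
The median deposited p-value (points) and its quartiles (bars) are plotted against the distance from the summits of the 64 regions, in bins of 250 bp, without the summit probes. The median is under 0.05 to 750 bp and reaches 0.475 in the last bin, between the median of the core (0.454) and that of all probes (0.512, dashed line).

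Regions were denser in the core of the chromosome, which in Streptomyces carries most essential genes, than in its arms. The core from 1.5 to 6.4 Mb held 50 of the 64 regions (78.1%) and 56.5% of the probes. This amounts to 10.2 regions per Mb in the core and 3.74 per Mb in the arms, a ratio of 2.73. Circular shifts of the summits gave 50 or as extreme a count with a two-sided permutation p of 0.0249 over 36043 shifts. The shifts gave counts from 23 to 50, with a mean of 36.1, so this p is the share of shifts that tied with the observed 50. Shifts by nearly the same number of steps give nearly the same count, so the shifts are not independent placements. The left arm held 6 regions and the right arm 8, and no region lay in the first 0.5 Mb of the sequence. Of the 25 strongest regions 21 lay in the core, a share at least as high as the 78.1% of all regions, and the rest lay in the arms. The permutation p moved with the settings even where the share did not: with at least 3 called probes per region the share was 78.6% with p = 0.17. With the middle part of the sequence, holding 33% of the probes, as the core the share was 46.9% with p = 0.411 (both permutation tests by circular shifts).

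Neighbouring summits were a median of 93.5 kb apart. The closest pair lay 1820 bp apart, at 6270260 and 6272080, and 4 pairs of neighbouring summits lay under 10 kb apart. The longest distance between neighbouring summits was 662 kb, from 7488579 to 8150712. Summits fell on forward probes in 37 of 64 regions (57.8%), against 51.9% of all probes, a difference that did not pass Fisher's exact test (two-sided p = 0.382).

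The general level of the p-values also varied along the chromosome. In the authors' deposited table the median p was 0.454 in the core, 0.642 in the left arm and 0.624 in the right arm. It fell from 0.715 in the first 0.5 Mb to 0.433 between 3.0 and 3.5 Mb in the authors' deposited table. It was 0.714 in the part beyond 8.5 Mb of the authors' deposited table. Between 5050423 and 5332492, a stretch of 282 kb and 1158 probes, the median p in the authors' deposited table was 0.287, against 0.463 in the 100 kb on either side. That stretch held 14 called probes and 4 regions.

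**Figure D4:**
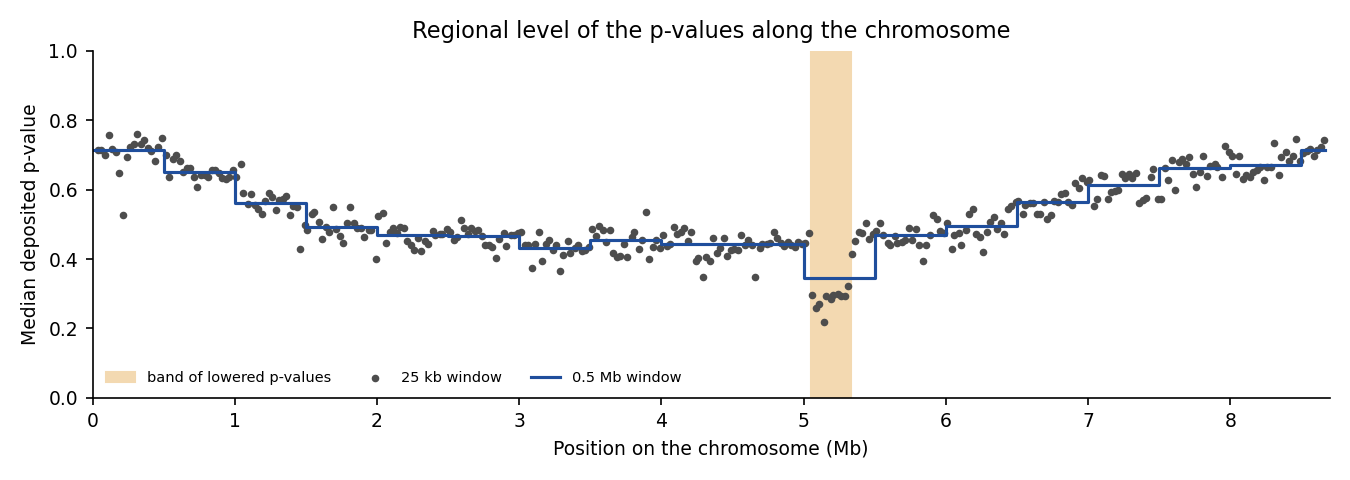
The median deposited p-value is plotted along the chromosome (Mb) for windows of 25 kb (points) and 0.5 Mb (line). The 0.5 Mb median is 0.715 at the left end and 0.714 at the right end, the median over the core is 0.454, and it is 0.287 in the shaded stretch from 5050423 to 5332492.

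At the other end of the scale, high p-values were fewer than low ones. Whether a p near the upper end stands for a difference in the other direction depends on the sidedness of the test, which is not given. The authors' deposited table holds 536 probes with p under 0.05 and 96 with p above 0.95. A uniform distribution would put 1802 in each, so both ends held fewer probes than that. A two-sided test of differences centred on 0 would spread p-values evenly or move them towards 0 or 1. The median p of 0.512, with 86.7% of p-values from 0.25 to 0.75, argues against such a test. When 1 minus p was adjusted by the Benjamini-Hochberg method, 4 probes passed 0.05, against 540 after the p-values were centred along the chromosome and rescaled to their own spread. The 4 were the probe at 594539, with a p of 0.999998 in the authors' deposited table, and 3 neighbouring probes starting at 5474287, 5474467 and 5475037. These lay inside a run of 5 probes from 5473907 to 5475336 whose lowest p in the authors' deposited table was 0.992. The nearest called probe lay 37031 bp from the middle of that run. The probe at 594539 lay between 0.5 and 1.0 Mb, where the median p was raised (0.652). The run lay between 5.0 and 5.5 Mb, where the median p was 0.346.

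The lone called probes had higher p-values than the stronger regions. Their median p in the authors' deposited table was 1.43e-05, against a median summit p of 1.50e-23 for the regions, and all 39 had a higher p than the median region. A summit is the lowest of at least 2 called probes, and a lone probe has no called probe with its midpoint within 1000 bp. Part of the difference is therefore set by the choice of the groups. The ranges overlapped: the lowest p of a lone probe in the authors' deposited table was 1.03e-14, at 1529104. That is below the summit p of 3.43e-13 for the region at 6271860 to 6274779. The lone probes at 1919096 and 1921420 were neighbouring probes 2324 bp apart, so a gap without probes kept these called probes from being joined.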

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

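The count of 273 called probes was 234 at an adjusted p under 0.01 and 284 under 0.10. The count of 64 regions was 57 and 67 under the same settings, 73 with a gap of 500 bp and 64 with a gap of 2000 bp. With at least 1 called probe there were 103 regions, and with at least 3 there were 42. The following settings were chosen after seeing the data. A Bonferroni adjustment left 183 called probes and 44 regions. Centring the p-values on their neighbours left 264 called probes, all of them among the 273, and leaving out the band of lowered p-values left 258. Centring and then rescaling the scores by the spread of all probes (0.235, where a normal score has 1) called 1547 probes in 310 regions, including all 273, and 540 probes at the opposite end. The narrow spread enters by construction, since 86.7% of the deposited p-values lie from 0.25 to 0.75, where a uniform distribution would put 50%. The share of regions in the core missed the threshold of its permutation test in 4 settings: 78.6% with at least 3 called probes (p = 0.17), 76.6% with a gap of 2000 bp (p = 0.0797), 68.7% after centring and rescaling (p = 0.109) and 46.9% with the middle part of the sequence as core (p = 0.411). The cause was not tested. No paired analysis was possible because the table holds no value per array and the labels number only the wild-type arrays. Leaving out an array, other normalizations between arrays, minimum fold changes, the wild type without the mutant, promoter windows, gene list tests, dim-probe filters and removal of the bldD locus were not run, because they need values per array or gene positions.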

Other observations

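The tests below were chosen after the data had been seen, except that the predictions for the probe-orientation counts were written before those counts were made. All hypotheses were found and tested on the same table.

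Called regions gathered where the orientation of the probes changes from reverse to forward. Probes of one orientation come in runs of 9.68 on average, with 3721 changes along the chromosome against 17995 for orientations in random order. Of the 64 summits, 39 (60.9%) lay within 500 bp of a reverse-to-forward change, where 20.5% of all probes lie. Only 16 (25%) lay within 500 bp of a forward-to-reverse change, where 23.2% of probes lie, and 11 summits were near both. The excess depended on the distance: 14 summits against 5 lay within 200 bp and 45 against 33 within 1000 bp, where 39.2% and 40.8% of probes lie (one-sided permutation p of the difference = 0.00236 at 1000 bp). No other circular shift gave more than 37 near reverse-to-forward changes (one-sided permutation p = 2.77e-05, the smallest the shifts can give), and none a larger excess over forward-to-reverse changes (23, against a highest of 19). Among the 25 strongest regions, 16 lay near a reverse-to-forward and 5 near a forward-to-reverse change, and among the 39 lone probes 14 and 4.

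A candidate explanation for these 39 summits is that probes were designed along the coding strand, so that a reverse-to-forward change marks the space between divergent genes, where promoters face each other, and a forward-to-reverse change the space between convergent gene ends. An effect of probe spacing or design that was the same at any change of orientation would raise both kinds alike. The 16 summits within 500 bp of forward-to-reverse changes compare with 14.8 expected from shifts (one-sided permutation p = 0.412). The difference between the kinds at each of the 3 distances argues against such an equal effect as the whole cause. The layout differed between the kinds, however. Within 200 bp of a reverse-to-forward change lay 7.04% of probes, and within 200 bp of a forward-to-reverse change 10.7%. An effect that differs between the kinds was not tested. The prediction had asked for a count at or below the shift mean, which 16 did not meet. That bound was too strict for an equal effect, which needs equal excess on both sides. Whether orientation follows the coding strand stays untested here, since no gene positions on this build were used.

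The stretch from 5050423 to 5332492 stood out in a scan for shifted runs of probes (score 6.84, next 5.39 at 185507 to 214433). Strongly called probes inside it do not account for the shift, since without probes at p under 0.05 its median p was still below that of its flanks (difference -0.175). Only 1.21% of its probes were called, too few to move a median far, so this outcome was largely set in advance. The step at its edges was 0.48 on the normal-score scale at the left and 0.40 in size at the right, against a median of 0.05 and a 99th percentile of 0.25 at 33670 places over 100 kb away. The right edge did not exceed the highest step elsewhere, 0.41, at the start of the next band of the scan (185507). Because the scan chose the edges for their contrast, these steps alone do not decide whether a smooth drift is the cause. On a fixed grid of 25 kb windows the median p fell from 0.474 at 5.04 Mb to 0.297 at 5.06 Mb. It was 0.322 at 5.31 Mb, 0.413 at 5.34 Mb and 0.451 at 5.36 Mb. A change nearly as large, from 0.528 to 0.695, lay at the next band of the scan. The fall between neighbouring windows argues against a smooth drift as the whole cause of the left edge. All 28 windows of 10 kb in the stretch (100%) had a median p below the lowest flank window, 0.427. The window medians in the stretch ranged from 0.181 to 0.369, so it was low throughout but not level. A segment whose DNA amount differed between the compared preparations could give a band that is low throughout. If ratios to the strain's own total DNA were compared, a difference in copy number between the strains would largely cancel. Without values for each channel such a segment cannot be told apart from other causes, and the band was chosen for its low values. A biological difference between the strains stays open and untested.

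The lone probes were mostly not isolated. The median over lone probes of the mean p of their nearest probes within 500 bp was 0.0363, against 0.512 over circular shifts (one-sided permutation p = 2.77e-05, the smallest possible), and 21 of the 35 with any probe within 500 bp had one there at p under 0.05. The other 4 lone probes could not be tested. This argues against isolated bad spots for those 35 as a set. For 3 of them both nearest probes had p over 0.3, and a bad or cross-hybridising spot is a candidate explanation there. They start at 7909547 (deposited p 9.49e-12, neighbours at 0.492 and 0.685), 5784709 (3.65e-05, neighbours at 0.474 and 0.526) and 6275999 (0.000123, neighbours at 0.314 and 0.353). The probe at 6275999 is the least clear of the 3, since it follows the widest region. Both of its neighbours also lay below the median p of 0.495 between 6.0 and 6.5 Mb.

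Probes with p above 0.97 numbered 60 and formed 22 adjacent pairs, against a highest of 3 in 100000 random placements (permutation p = 1e-05, the smallest possible). Random placement ignored the higher level of p-values near both ends of the sequence (0.5 Mb medians of 0.715 and 0.714). It therefore gives too few pairs, by an amount that was not measured. The longest runs held 6 probes at 4586942 to 4587788, whose middle lay 1062 bp from a called probe, and 5 probes at 5473907 to 5475336.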
